A study of Mus musculus with 6 samples.

How the data were processed

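RNA of 6 whole fetal livers was measured on 6 arrays, 3 from wildtype and 3 from Klf1 knockout embryos at embryonic day 13.5, and each array was assigned to its genotype from its labels. Per the labels' protocols, livers were dissociated, RNA was extracted with TRI-Reagent and RNeasy columns with DNase treatment, and biotin-labelled material was hybridised to Affymetrix Mouse Gene arrays in 1 colour. The deposited values are probe set intensities made by the authors with RMA in Affymetrix Power Tools 1.8.6, per the submitters' processing notes; the genome build and annotation used upstream are not given in the sources used here. RMA corrects background, equalises the distributions of the arrays and summarises the probes of each set, so a change in total RNA per liver cannot be seen in these values. The values ran from 5.6 to 27245 with a median near 105 per array, a linear scale, and log2 was taken before any test. No further normalization and no filter on dim probe sets was applied. The descriptions give each array an embryo number of its own; whether embryos came from separate litters is not stated, so p-values measure the spread between these embryos.

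Probe sets were named through the platform's annotation table. Of 34760 probe sets, 21640 had 1 gene, 1321 had several and 11799 had none named here. A symbol was updated where its Entrez identifier gave another one in the GRCm38.p6 gene table; 0 changed, and 87 probe sets had an identifier outside that table, which was used only for names and for the order of neighbouring genes. A gene was represented by its brightest single-gene probe set, which left 19937 genes; 954 genes had more than 1 such probe set, and in 3, Adgrl2, Bcr and Zdhhc20, probe sets were called in opposite directions. Probe sets with several genes or none stayed out of the gene counts.

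Knockout was compared with wildtype by lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, with group as the sole term and Benjamini-Hochberg adjustment over all genes. An exact permutation test of 3 against 3 arrays cannot go below p = 0.10, so single values were tested only within this model. The 27 gene lists were written from textbook knowledge before the data were examined: 25 biological lists with measured members, the adult globins with 0 measured, and a list of sex-linked genes as a check of the embryos. Of 584 listed symbols 539 were measured. Each list was described by counts of called members, adjusted over all genes and over the list alone, and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 25 lists. Camera compares a list with the other genes. The p with an estimated correlation rose even in lists whose estimate was below the preset. It therefore does not show the effect of correlation alone. Fry tests whether the genes of a list move, on balance, in 1 direction.

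Genes named in the text followed a rule fixed before the data were examined: Klf1; the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap; all measured globins; and up to 4 called members with the largest change per list, or the 2 with the smallest p where none was called. Alas1, Rbl2 and Gata1 were named after their values were seen.

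The fit was tested on simulated values for the 19937 genes of this comparison, with 50 genes changed at each size. It called 72% of genes changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 11 false calls among 193. Far fewer genes were changed than the 3809 called in the real data, and the noise of each gene was drawn independently. These rates therefore need not carry over to the real comparison. Camera called 13 of 13 simulated lists shifted by 0.4 and 0 of 12 lists left alone; the simulated genes were independent of each other, which genes of a tissue are not.

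Alternatives were quantile normalization, centring on the 75th percentile or on the housekeeping list, filters on dim genes, the mean of the probe sets or every probe set, other variance models, array weights, a replicate block, a covariate for Y-linked genes, stricter thresholds and leaving out each array. Centring on deviations of the housekeeping genes was added after the data were seen.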

Results

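Gene expression was measured in whole fetal livers of FVB/NJ mice at embryonic day 13.5, when the liver is the main site of red cell formation. Livers of 3 wildtype embryos were compared with livers of 3 Klf1 knockout embryos; Klf1 is an erythroid Krüppel-like transcription factor. Each liver was hybridised to its own 1-colour Affymetrix gene array, so n = 3 per group throughout. The median intensity per array lay between 104.5 and 109.8, with the lower quartile between 35.7 and 38.0 and the upper quartile between 391 and 418. The comparison asks which genes differ in RNA level between knockout and wildtype livers. In a whole liver a lower level can reflect fewer cells of a kind or less RNA per cell. These were not told apart for the red cell genes below. Changes are given as knockout minus wildtype on the log2 scale, with the standard error of the limma fit after ±, and a gene is called at a Benjamini-Hochberg adjusted p under 0.05. The number of arrays limits the precision, and the livers also hold cells other than red cell precursors, whose markers are given below with the rest.

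The targeted gene itself was lower in every knockout array. The single-gene probe set of Klf1 read 10.59, 10.58 and 10.76 in wildtype replicates 1, 2 and 3, against 9.05, 9.38 and 9.12 in the knockout replicates, a change of -1.46 ± 0.10 (limma adjusted p = 3.7e-06). The labels do not state which part of the gene was altered, so transcript from outside that part would leave signal on this probe set, and the value may check nothing about the loss of the protein.

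The largest falls included several genes of the red cell lists. Nxpe2, one of the erythroid differentiation genes, fell by 5.77 ± 0.08 (adjusted p = 4.1e-11), from 12.95 ± 0.05 to 7.18 ± 0.11 (SD, n = 3). Fn3k, a kinase that removes sugar from glycated proteins, fell by 4.70 ± 0.16, Sowaha by 4.54 ± 0.09 and Slc22a4, an organic cation transporter, by 3.99 ± 0.16. Dmtn, an actin-bundling protein of the red cell membrane, fell by 3.73 ± 0.11, and Ackr1, the Duffy antigen, fell by 3.25 ± 0.12. Tspo2, Tspan8, Slc43a1, Mgll, Mgst3 and F930017D23Rik completed the 12 largest falls, with changes from -3.86 to -3.36.

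The largest rises were smaller. Hecw1 rose by 3.13 ± 0.11 and Car1, a carbonic anhydrase of red cells, by 2.95 ± 0.10, from 10.08 ± 0.19 to 13.03 ± 0.03 (SD, n = 3). Alox5, the lipoxygenase of leukotriene synthesis, rose by 2.62 ± 0.09, Egln3, an oxygen-sensing prolyl hydroxylase, by 2.35 ± 0.11, and Bnip3, a mitophagy receptor, by 2.09 ± 0.18. Lrrc39, Btn1a1, Glt28d2, Cda, Ciart, Hbb-bh1 and Fam160a1 completed the 12 largest rises, from 2.87 in Lrrc39 to 1.89 in Hbb-bh1 and, lowest, Fam160a1, which went from 6.41 to 8.21. All of these 24 genes had limma adjusted p of 1.5e-05 or less.

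Of 19937 genes tested, 3809 were called, 2163 higher and 1646 lower in the knockout, so 43.2% of calls were lower, and between 41.7 and 46.1% with 1 array left out. Among the 312 genes changed at least 2-fold the split was the other way, with 105 higher and 207 lower, and at 4-fold 9 were higher and 47 lower. In 3791 of the called genes the groups did not overlap; over all genes this held for 37.5%, where chance gives 10%. The split of small changes depended on scaling: centring each array on its 75th percentile made 55.5% of calls lower, and centring on the housekeeping genes called 11616 genes, 92.2% of them lower, with the median of all genes at -0.26 in place of -0.02. Housekeeping centring lowered the change of every gene by the same amount and called 10714 of the 19937 genes lower. List counts given below with housekeeping centring carry that shift. Its centre is the level of the middle housekeeping gene, which was B2m on 2 wildtype arrays and Ywhaz on the others. With Ywhaz in the middle it was 12.15 on wildtype replicate 3 and 12.41 to 12.46 on the knockout arrays. The change of middle gene alone thus does not account for the shift. Pgk1, the only housekeeping gene called, also crossed the centre. It read 11.54 to 11.86 on the wildtype arrays, below the centre, and 12.55 to 12.67 on the knockout arrays, above it. This crossing moves the middle up in rank on the knockout arrays. How much of the shift it gives was not tested. Centring on the deviations of the same genes, added after the data were seen, called 2937 genes, 43.1% of them lower. The count fell to 2409 without knockout replicate 2 and to 2414 without knockout replicate 3.

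**Figure D1:**
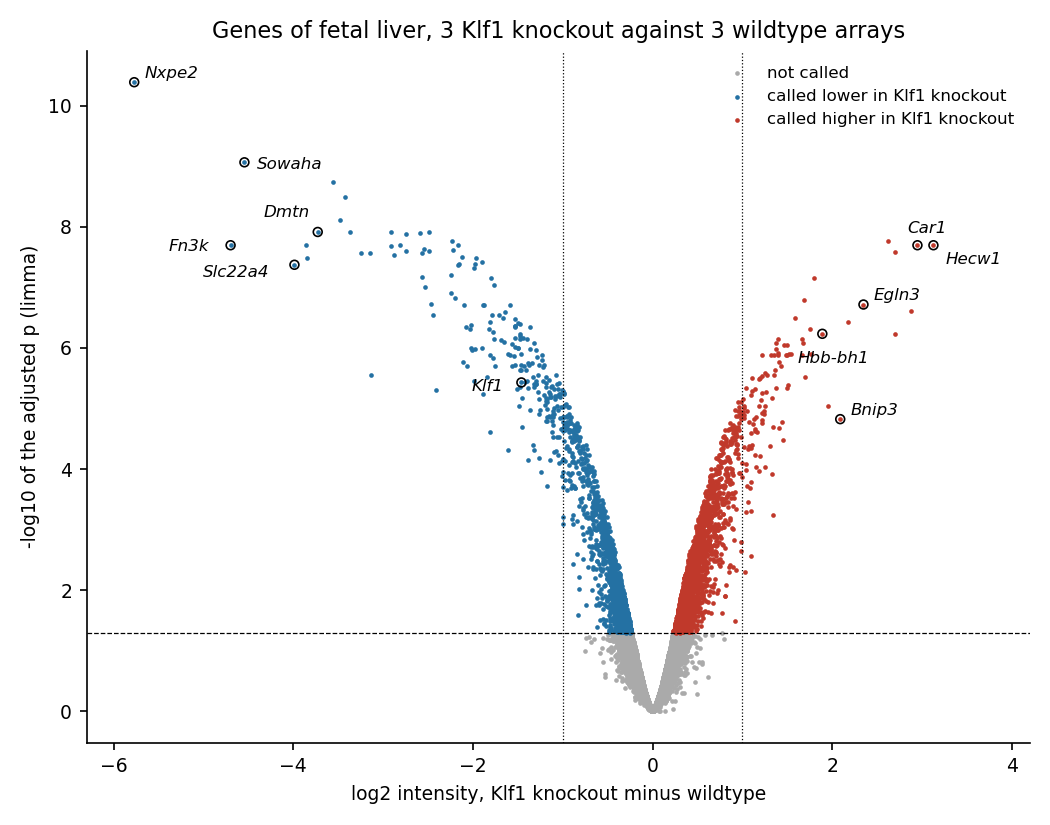
Each point is 1 of 19937 genes, with the log2 change of Klf1 knockout against wildtype livers on the horizontal axis and the -log10 of the limma adjusted p on the vertical axis; dotted lines mark a 2-fold change and the dashed line an adjusted p of 0.05, and named genes are circled. The falls reach -5.77 (Nxpe2), the rises 3.13 (Hecw1).

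Genes of the red cell membrane fell almost throughout. Of 28 measured members of the red cell membrane and cytoskeleton list, 22 fell, 0 rose and 6 were not called, and the counts were the same adjusted over the list alone. Besides Dmtn and Tspo2, the amino acid transporter Slc43a1 fell by 3.55 ± 0.08 and the adhesion molecule Icam4 fell by 2.10 ± 0.10. The list median was -0.82, and camera called the list (adjusted p = 1.5e-20; adjusted p = 0.176 with an estimated correlation). Among 36 erythroid differentiation genes 26 fell and 4 rose, or 27 and 4 adjusted over the list alone; Mgst3, a glutathione transferase, fell by 3.42 ± 0.08 and Fn3krp by 2.81 ± 0.10, while Car1 rose. Camera called this list too (adjusted p = 2.1e-15; adjusted p = 0.207 with an estimated correlation).

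Heme synthesis genes were lower. Of 11 measured, 7 fell and 1, Alas1, the general form of the first enzyme, rose by 0.33, a call lost without knockout replicate 2 or 3; adjusted over the list alone 7 fell and 2 rose, and with housekeeping centring 9 fell and 0 rose. Slc25a38, the mitochondrial glycine carrier, fell by 1.06 ± 0.08, the erythroid first enzyme Alas2 by 0.97 ± 0.08 and Alad by 0.89 ± 0.10, and the heme-associated transporter Abcb10 fell from 11.31 to 10.31. Camera called the list (adjusted p = 0.00028; adjusted p = 0.176 with an estimated correlation). Iron genes went both ways: among 20, 6 fell and 3 rose, adjusted over the list alone likewise, and 12 fell and 2 rose with housekeeping centring. The mitochondrial iron importer Slc25a37 fell by 1.97 ± 0.07, the transferrin receptor Tfrc by 1.30 ± 0.08 and the hormone Erfe by 1.27 ± 0.10, while the heme exporter Flvcr1 rose by 1.38 ± 0.10. Camera did not call the iron list (adjusted p = 0.072; adjusted p = 0.369 with an estimated correlation), while fry called it lower (adjusted p = 0.0014).

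Nuclear clearance and autophagy genes had 9 of 23 lower and 3 higher, or 10 and 4 adjusted over the list alone; without knockout replicate 3 there were 6 and 0, and with housekeeping centring 14 and 0. The nuclear exporter Xpo7 fell by 2.20 ± 0.10, the ubiquitin ligase Trim58, which also stands in the erythroid differentiation list, by 1.18 ± 0.09, Atg4d by 1.05 ± 0.09 and the autophagy kinase Ulk1 by 0.77 ± 0.09. Camera called the list narrowly (adjusted p = 0.0381; adjusted p = 0.373 with an estimated correlation), and did not call it without wildtype replicate 1 (adjusted p = 0.0709) or without knockout replicate 1 (adjusted p = 0.0915).

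Of the globins measured by probe sets of their own, the embryonic beta-like gene Hbb-bh1 rose by 1.89 ± 0.10 (adjusted p = 5.9e-07), from 10.08 ± 0.16 to 11.97 ± 0.13 (SD, n = 3). Hbq1a and Hbq1b, near-identical copies whose signals may not be separable, both fell, the first from 6.64 to 5.64 and the second by 0.51 ± 0.09. The embryonic genes Hbb-y, at 0.11 ± 0.10 with a level near 13.6 in wildtype, Hba-x, at -0.40 ± 0.21, and Hbb-bh2, at -0.04 ± 0.08, were not called. Hbb-y lay near the top of the range, where changes can be compressed. It turned to -0.13 with housekeeping centring, and Hbb-bh2 turned to 0.013 with quantile normalization. Hba-x was called at -0.63 without knockout replicate 3 (adjusted p = 0.0378) and with housekeeping centring (adjusted p = 0.0394), which also called Hbb-bh2 at -0.28 (adjusted p = 0.0244); with 1 array left out Hba-x ran from -0.63 to -0.22. Of the 6 measured members of the embryonic globin list 1 rose, Hbb-bh1, and 2 fell, Hbq1a and Hbq1b, also adjusted over the list alone. With housekeeping centring 1 rose and 4 fell. The median of this list was -0.22, its mean 0.01, camera's direction down and that of fry up, and neither called it (adjusted p = 0.627 and 0.338; adjusted p = 0.723 with an estimated correlation). The adult globin list had 0 members measured alone.

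Erythroid transcription factors split by member. Sox6, which represses embryonic globin genes in definitive red cells, fell by 2.75 ± 0.10, and Bcl11a, a repressor of the same genes, fell from 11.59 to 10.59. Zbtb7a fell by 1.11 ± 0.10 and Lmo2 by 1.01 ± 0.07. Gata1, at -0.02, was not called, and Gata2, an early progenitor factor, rose by 0.65 ± 0.11. Of 26 genes 11 fell and 3 rose, also adjusted over the list alone, and 20 fell and 2 rose with housekeeping centring (list camera adjusted p = 0.0012; adjusted p = 0.241 with an estimated correlation). In the Klf and Sp families 9 of 24 fell, Klf1 among them, and 3 rose, also adjusted over the list alone; with housekeeping centring 19 fell and 1 rose. Klf3 fell by 2.59 ± 0.08, Klf11 by 1.03 ± 0.09 and Klf10 by 0.78 ± 0.10. Camera called this list (adjusted p = 0.0017; adjusted p = 0.176 with an estimated correlation).

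**Figure D2:**
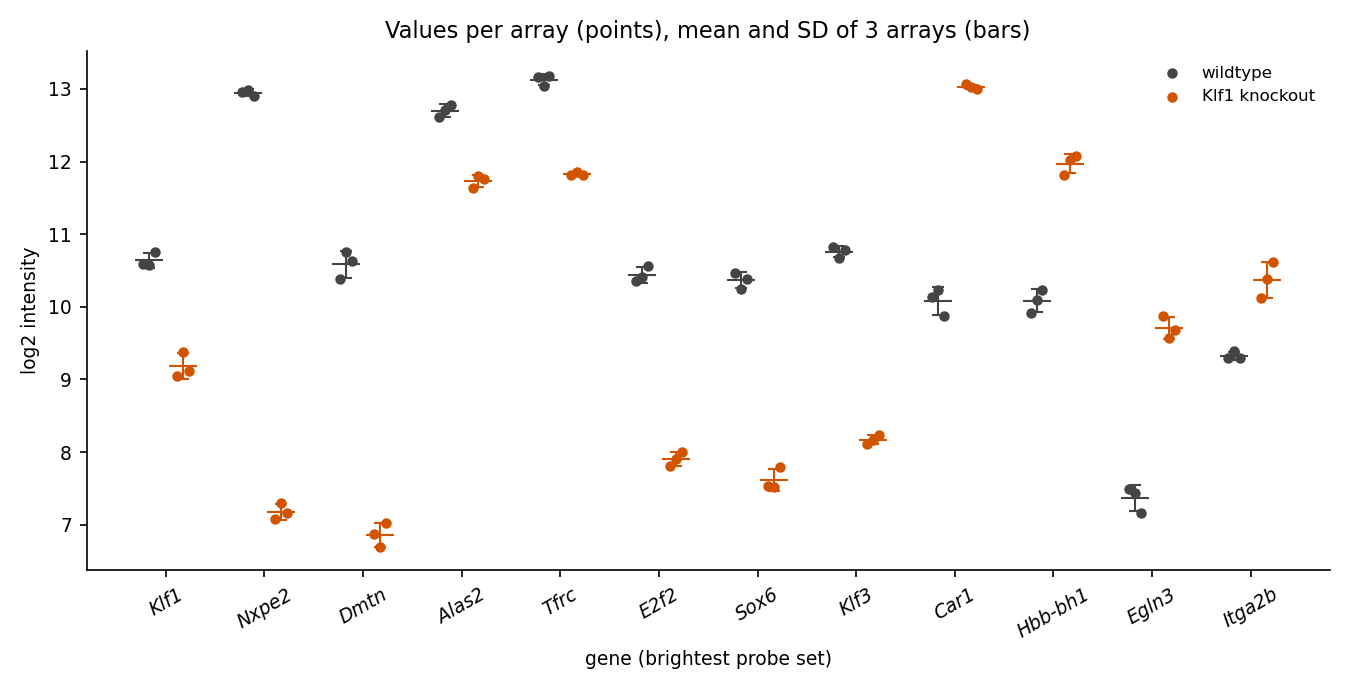
Log2 intensity of 12 genes on each of 3 wildtype and 3 Klf1 knockout arrays (points), with the mean and SD per group as bars. In each gene shown the groups do not overlap, with changes from -5.77 (Nxpe2) to 2.95 (Car1).

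Cell cycle genes were lower, led by E2F factors. E2f2, an activator of S-phase genes, fell by 2.54 ± 0.09, from 10.44 ± 0.11 to 7.90 ± 0.10 (SD, n = 3); E2f4 fell by 1.40 ± 0.08, E2f8 by 0.82 ± 0.08 and the cyclin gene Ccne2 from 10.46 to 9.46. In the list of G1/S and replication, 15 of 35 genes fell, 1 (Rbl2) rose and 19 were not called; 16 fell and 1 rose adjusted over the list alone (list camera adjusted p = 1.5e-05; adjusted p = 0.373 with an estimated correlation). In the G2/M list 11 of 27 fell and 0 rose, also adjusted over the list alone, with smaller sizes: the phosphatase gene Cdc25b fell by 0.88 ± 0.08 and Prc1 by 0.63 ± 0.07 (list camera adjusted p = 6.4e-06; adjusted p = 0.281 with an estimated correlation). The G2/M falls numbered 6 to 9 with any 1 array left out, 6 without knockout replicate 1 or 3, and 7 after quantile normalization. With housekeeping centring all 27 fell, as did 31 of the 35 G1/S genes, with 1 rising. Less the median of all genes, the G2/M median was -0.16 with and without that centring. CDK inhibitors and p53 targets, which restrain the cycle, were also lower, with 6 of 17 falling and 2 rising (0 without knockout replicate 2 or 3), or 6 and 3 adjusted over the list alone, and 13 and 0 with housekeeping centring. The INK4 inhibitors Cdkn2c and Cdkn2d fell by 1.47 ± 0.09 and 1.11 ± 0.09 (list camera adjusted p = 0.0062; adjusted p = 0.176 with an estimated correlation).

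Genes of the hypoxia response were higher. Of 21 members 16 rose, 2 fell and 3 were not called, or 19 and 2 adjusted over the list alone, with a median of 0.53. Besides Egln3 and Bnip3, the glucose transporter gene Slc2a3 rose by 0.95 ± 0.08, while Slc2a1, the main glucose transporter gene of fetal red cells, fell by 1.99 ± 0.08. With housekeeping centring 13 members still rose and 2 fell. Camera called the list (adjusted p = 8.2e-11; adjusted p = 0.153 with an estimated correlation). In the list of red cell antioxidant and glycolytic enzymes 9 of 20 rose and 6 fell, also adjusted over the list alone. The red cell pyruvate kinase gene Pklr fell by 2.17 ± 0.07, while the glycolytic genes Aldoa, Pgk1 and Pfkm rose by 1.22 ± 0.08, 0.88 ± 0.10 and 0.82 ± 0.08. Camera did not call the list (adjusted p = 0.178; adjusted p = 0.563 with an estimated correlation). Its median of 0.10 turned to -0.13 with housekeeping centring, where 5 members rose and 9 fell.

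Apoptosis regulators had 4 of 21 higher (2 without knockout replicate 2) and 4 lower, or 5 and 8 adjusted over the list alone; 13 of the 21 changes were negative, and with housekeeping centring 2 rose and 14 fell. Bcl2l1, the survival gene of late erythroblasts, fell by 1.03 ± 0.08, and the death-promoting gene Bcl2l11 rose by 0.45 ± 0.08. Camera did not call the list (adjusted p = 0.347; adjusted p = 0.469 with an estimated correlation), while fry called it lower (adjusted p = 0.00558). Among 24 interferon response genes 5 rose and 1 fell, or 6 and 1 adjusted over the list alone. Rsad2 fell by 1.81 ± 0.16 and the RNA sensor gene Ddx58 rose by 0.81 ± 0.19 (list camera adjusted p = 0.383; adjusted p = 0.792 with an estimated correlation). The rises numbered 2 without wildtype replicate 1, 1 without wildtype replicate 2 or knockout replicate 2, 2 with the added centring on deviations, and 0 without moderation or over every probe set. Camera called the list higher without knockout replicate 3 (adjusted p = 0.0099) and did not call it with any other array left out. With housekeeping centring 1 rose and 8 fell. The list median of 0.02 turned to -0.02 and -0.21 with 75th percentile and housekeeping centring.

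Markers of the other blood cells of fetal liver did not move alike. All 24 measured megakaryocyte and platelet genes had positive changes and 22 rose, or 23 adjusted over the list alone, with a median of 0.66. The matrix protein gene Thbs1 rose by 1.26 ± 0.09, the integrin gene Itga2b by 1.05 ± 0.12, the platelet receptor gene Clec1b by 0.84 ± 0.12 and the platelet lipoxygenase gene Alox12 by 0.79 ± 0.11 (list camera adjusted p = 1.2e-15; adjusted p = 0.25 with an estimated correlation). With housekeeping centring 17 of them rose and 0 fell, and without moderation 8 rose. All 20 granulocyte genes had positive changes, but 6 rose, or 16 adjusted over the list alone, with 4 to 10 rising when 1 array was left out, 2 with housekeeping centring and 0 without moderation; the granule genes Mpo and Elane rose by 0.58 ± 0.10 and 0.54 ± 0.11 (list camera adjusted p = 2.5e-06; adjusted p = 0.241 with an estimated correlation). Macrophage genes were lower, with 10 of 25 falling and 1 rising, or 13 and 1 adjusted over the list alone; 8 to 13 fell with 1 array left out, 4 without moderation and 22 with housekeeping centring. Lgmn fell by 0.94 ± 0.11, Cd5l by 0.90 ± 0.13 and Spic and Adgre1, genes of red pulp and island macrophages, by 0.67 ± 0.15 and 0.66 ± 0.13 (list camera adjusted p = 4.6e-05; adjusted p = 0.351 with an estimated correlation).

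Of 19 stem and progenitor genes 7 rose and 0 fell, also adjusted over the list alone, with Slamf1 at 1.32 ± 0.08 and Meis1 at 0.46 ± 0.10 (list camera adjusted p = 0.0142; adjusted p = 0.37 with an estimated correlation); 3 rose without wildtype replicate 2 or knockout replicate 2 and 4 with the added centring on deviations. With housekeeping centring 2 rose and 7 fell, and the median of 0.12 turned to -0.11. Mast cell and basophil genes had 1 of 11 higher, Slc18a2 at 0.53 ± 0.13 (not called without wildtype replicate 1 or knockout replicate 2), also adjusted over the list alone (list camera adjusted p = 0.455; adjusted p = 0.563 with an estimated correlation). Lymphoid genes had 1 of 14 higher, Il7r at 0.71 ± 0.09, and 1 lower, Cd3d at -0.30 ± 0.09 (not called without wildtype replicate 1 or 2 or knockout replicate 1 or 3), also adjusted over the list alone (list camera adjusted p = 0.591; adjusted p = 0.755 with an estimated correlation). With housekeeping centring 0 mast cell and basophil genes rose and 8 fell, and 1 lymphoid gene rose and 10 fell. Many genes of these lists were dim. The filter on dim genes at the median level left 2 of 11 mast cell and basophil genes and 2 of 14 lymphoid genes. The filter at the 25th percentile left 5 and 9. Cd3d averaged 4.91 in wildtype and lay below the lower quartile on every array. The few calls in these lists thus do not show that these cells were unchanged.

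Markers of the liver's own tissue moved little. Of 26 hepatoblast and hepatocyte genes 5 fell, or 6 adjusted over the list alone, and 0 rose, with Fga at -0.39 ± 0.12 and Apom at -0.38 ± 0.10 (list camera adjusted p = 0.0216; adjusted p = 0.536 with an estimated correlation; fry adjusted p = 0.171); the list was not called after quantile normalization (adjusted p = 0.0815), without wildtype replicate 3 (adjusted p = 0.13) or without knockout replicate 2 (adjusted p = 0.053). The number of hepatoblast genes that fell was 0 without wildtype replicate 3, without knockout replicate 2, without knockout replicate 3 and with the added centring on deviations, 1 after quantile normalization and 19 with housekeeping centring. Of 20 endothelial genes 4 rose and 0 fell, or 6 and 2 adjusted over the list alone, with Flt1 at 0.51 ± 0.11 (list camera adjusted p = 0.072; adjusted p = 0.681 with an estimated correlation); with housekeeping centring 0 rose and 4 fell, and with 1 array left out 1 (without knockout replicate 3) to 9 (without wildtype replicate 3) rose. Of 24 mesenchymal and mesothelial genes 3 fell, and 0 adjusted over the list alone, with 0 falling without knockout replicate 2, 7 without wildtype replicate 1 and 16 with housekeeping centring. Lum was at -0.74 ± 0.18, from -0.93 to -0.48 with 1 array left out, and was not called without knockout replicate 2 (adjusted p = 0.0525). Camera did not call the mesenchymal list (adjusted p = 0.057, or 0.658 with an estimated correlation). It called that list lower after quantile normalization (adjusted p = 0.0254) and without wildtype replicate 1 or knockout replicate 3 (adjusted p = 0.0017 and 0.00621). The endothelial list was called higher by camera without wildtype replicate 3 or knockout replicate 1 (adjusted p = 0.000445 and 0.0247). Further settings that called these lists are given below. Of 13 housekeeping genes Pgk1 rose and 12 were not called, also adjusted over the list alone (list camera adjusted p = 0.627; adjusted p = 0.829 with an estimated correlation), and the list median of 0.02 turned to -0.02 and -0.21 with 75th percentile and housekeeping centring, the latter with 1 higher and 7 lower.

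**Figure D3:**
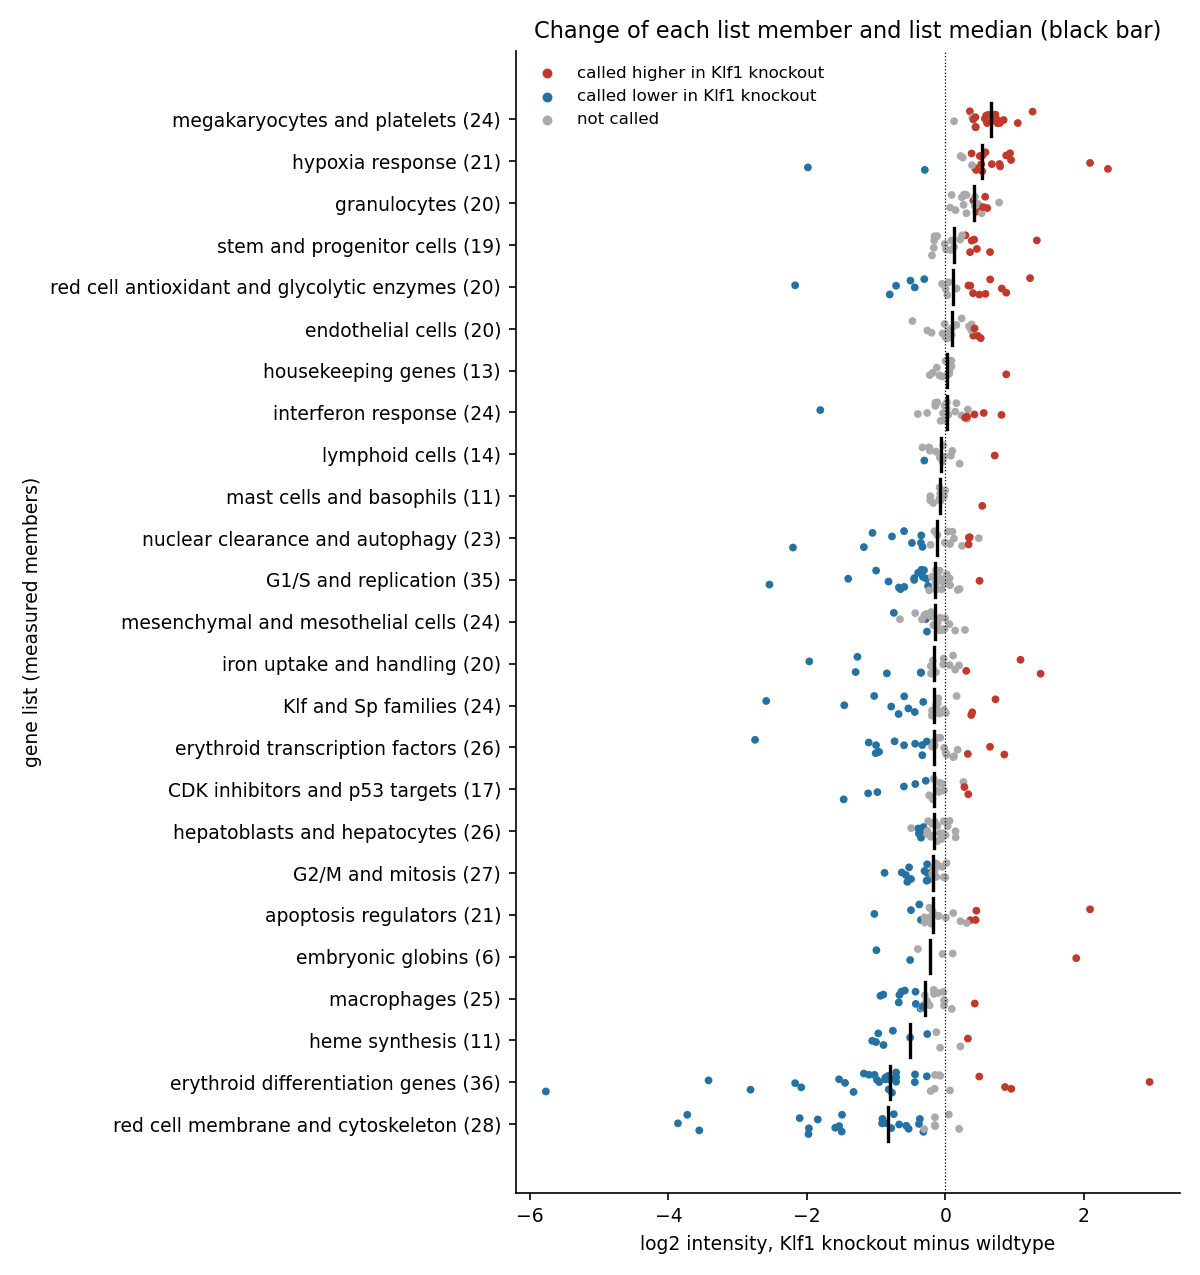
Each point is a measured member of 1 of the 25 lists, placed by its log2 change between Klf1 knockout and wildtype livers, coloured by its limma call, with the list median as a black bar. The medians run from -0.82 in the red cell membrane list to 0.66 in the megakaryocyte list; with housekeeping centring those of the stem, antioxidant and glycolytic, endothelial, housekeeping and interferon lists turn below 0.

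In all, camera with its preset correlation called 15 of the 25 lists, 11 lower and 4 higher, and fry called 16. With an estimated correlation camera called 0, with 6 lists at an unadjusted p under 0.05, and groupings of the 6 arrays that mix the genotypes gave between 5 and 13 called lists with the preset correlation. The same groupings called at most 1 gene. Each of them held unequal numbers of the genotypes on its sides. Part of the genotype difference thus stayed in the comparison and part entered the spread, so these counts are not those of groups without a difference.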

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

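The tests below on probe sets outside the gene comparison were all chosen after their values were seen. They were picked out because these probe sets name no gene or several, and so stayed out of the gene counts of the main comparison, yet differed between the genotypes. Their limma values come from a fit of all 34760 probe sets, adjusted over these and not over the 19937 genes of the main comparison.

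The largest change on the arrays was in a probe set with no gene named here. Probe set 10608710 changed by -8.64 (limma adjusted p = 1.4e-08), from 13.45 ± 0.02 in wildtype, among the brightest signals measured, to 4.81 ± 0.04 in the knockout (SD, n = 3), with no overlap between the groups. The knockout level lay below the lower quartile of every array, so the size of the fall may be understated. In all, 963 of 11799 probe sets with no gene named here were called, 481 higher and 482 lower, as were 76 of 1321 with several genes, 47 higher and 29 lower. In the same fit 2511 of 21640 probe sets with 1 gene were called, a larger share than in either of these kinds.

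The adult globin genes were measured by joint probe sets that each match several family members. The adult beta-globin set 10566254 changed by -2.85, from 13.03 ± 0.11 to 10.18 ± 0.33 (SD, n = 3; limma adjusted p = 0.00013), and the set 10566258 by -1.11, from 14.44 ± 0.04 to 13.33 ± 0.15 (limma adjusted p = 0.00064). The joint sets of the adult alpha-globin genes changed by -0.09 and -0.22 and were not called (limma adjusted p = 0.511 and 0.246), at levels between 13.6 and 14.4. The difference between the beta and alpha sets was not tested, and signals this bright lie near the top of the range, where changes can be compressed.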

How the results depend on the processing

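All alternatives were fixed beforehand, except centring on the deviations of the housekeeping genes, chosen after the data were seen; of the counts over other groupings of the arrays, those of genes were chosen after the result was seen. Of the comparisons of named genes across settings, 1940 kept direction and call, 142 lost the call, 4 gained it and 3 turned sign; for the lists 470 kept both, 28 lost the call, 18 gained it and 9 turned. Below, p is the adjusted p of the list, and except where construction explains a change the cause was not tested.

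With an estimated correlation all 15 called lists lost their call: heme synthesis, red cell membrane, Klf and Sp families and CDK inhibitors (0.176), erythroid differentiation (0.207), erythroid transcription factors and granulocytes (0.241), nuclear clearance and G1/S (0.373), G2/M (0.281), hypoxia (0.153), stem and progenitor cells (0.37), megakaryocytes (0.25), macrophages (0.351) and hepatoblasts (0.536). In the Klf and Sp families and the CDK inhibitors the estimated correlation was 0.0036 and -0.0346, below the preset 0.01. Their unadjusted camera p still rose, from 0.00075 to 0.0229 and from 0.0030 to 0.033. A higher correlation between members thus does not account for the lost calls of these lists. The estimated setting therefore differs from the preset one in more than the correlation. How much of the other lost calls comes from correlation between members was not tested. With fry, iron handling (0.0014) and apoptosis (0.00558) passed, hepatoblasts did not (0.171), and embryonic globins turned direction (0.338).

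Quantile normalization ended the call of hepatoblasts (0.0815), added mesenchymal genes (0.0254) and turned Hbb-bh2 to 0.013. With 75th percentile centring 55.5% of calls were lower and endothelial genes passed (0.0478). With housekeeping centring 11616 genes were called, 92.2% lower; nuclear clearance and hepatoblasts lost their call (both 0.126), antioxidant and glycolytic enzymes (0.0119) and endothelial genes (0.0138) passed, embryonic globins (0.778) and housekeeping genes (0.82) turned, as did Hbb-y (-0.13). This centring takes the level of the middle housekeeping gene, which was B2m on 2 wildtype arrays and Ywhaz on the other arrays. The centre was 12.15 to 12.23 in wildtype and 12.41 to 12.46 in knockout arrays. It was lowest, at 12.15, on wildtype replicate 3, where the middle gene was Ywhaz as on the knockout arrays. Pgk1 lay below the centre on all wildtype arrays and above it on all knockout arrays, which moves the middle up in rank. Centred on the genes' deviations from their own means, 2937 genes were called, 43.1% lower, with the median of all genes at -0.04; without Pgk1 2914 were called, 38.9% lower. With housekeeping centring the megakaryocyte median was 0.42 and the red cell membrane median -1.06; less the median of all genes, at -0.26, they were 0.68 and -0.80, as without it. Hba-x (-0.63) and Hbb-bh2 (-0.28) were called lower.

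The filter at the median level left 36.8% of calls lower; iron handling (0.0187) and mesenchymal genes (0.032) passed, stem and progenitor cells did not (0.0652), and interferon (0.815), lymphoid (0.128) and housekeeping genes (0.835) turned. The filter at the 25th percentile turned mast cells and lymphoid cells (both 0.947). Testing every probe set called 587 at 2-fold, among 34760 in place of 19937 tested, and mesenchymal genes passed (0.0366). With trend and robust, iron handling passed (0.0477). Without moderation 2083 genes were called, 45.8% lower. With array weights 46.8% were lower, nuclear clearance (0.0637) and hepatoblasts (0.0766) lost their call and endothelial genes passed (0.00951). With the Y-linked covariate 46.2% were lower and nuclear clearance was at 0.0522. An adjusted p under 0.01 left 1995 genes, and treat against 1.5-fold left 341, as stricter criteria must.

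Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.16, -0.22 and 0.18, and not every array correlated best with its own number. The replicate block called 3498 genes and Hba-x at -0.40 (adjusted p = 0.0117); nuclear clearance was at 0.0595, and endothelial (0.0269) and mesenchymal genes (0.0178) passed.

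Leaving out 1 array gave 2409 to 3749 genes, lowest without knockout replicate 2 (2409) and knockout replicate 3 (2414), 307 to 332 at 2-fold, 41.7 to 46.1% lower (highest without knockout replicate 1), and Klf1 at -1.56 to -1.39. Hbb-bh2 ran from -0.10 to 0.025, turning without knockout replicate 2, and Hba-x from -0.63 (called, without knockout replicate 3) to -0.22. List ranges were 0.0115 to 0.0915 for nuclear clearance (lost without wildtype replicate 1, at 0.0709, or knockout replicate 1), 0.00424 to 0.13 for hepatoblasts (lost without wildtype replicate 3, or knockout replicate 2, at 0.053), 0.000445 to 0.317 for endothelial genes (passing without wildtype replicate 3, or knockout replicate 1, at 0.0247), 0.0017 to 0.321 for mesenchymal genes (passing without wildtype replicate 1, or knockout replicate 3, at 0.00621) and 0.0099 to 0.766 for interferon (passing without knockout replicate 3, turning without knockout replicate 2, at 0.688).

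The other groupings of the 6 arrays called at most 1 gene against 3809, at most 1 at 2-fold against 312 and at most 13 lists against 15. In each case 1 of the 10 groupings, the genotypes, gave as many, and 10 groupings are too few for a share under 0.05. The other groupings also mix the genotypes unequally, which leaves part of the genotype difference in the comparison and part in the spread. Their counts therefore do not give the number of calls without a difference. Dim probe sets limit the rest: changes of genes near background may be understated, which was not tested.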

Other observations

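The test on a second hypoxia list was written before its result was seen; the other tests here were chosen after the result was seen, as were the genes of the next paragraph.

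Of 14 circadian clock genes looked at, 4 were called higher and 10 were not called, with changes of those from -0.07 to 0.22; over all genes 19.1% were called, and no enrichment was tested. Ciart, a clock repressor, rose by 1.95 ± 0.15, Cry2 rose by 0.95 ± 0.08, Per1 by 0.58 ± 0.09 and Arntl by 0.40 ± 0.11 (limma adjusted p = 0.0324). Of 13 immediate-early and feedback genes looked at, 5 fell and 1 rose: the phosphatase gene Dusp1 fell by 2.91 ± 0.10, from 10.71 to 7.79, Rgcc fell by 2.47 ± 0.11, Ier3 by 0.99 ± 0.10, Btg2 by 0.98 ± 0.07 and Socs3 by 0.68 ± 0.11. Jun rose by 0.81 ± 0.14, and Fos, Fosb, Egr1, Ier2, Junb, Nr4a1 and Atf3 were not called.

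The embryos differed in sex-linked genes. Wildtype replicate 2 and knockout replicate 1 had low Xist, at 5.59 and 5.84, and high Y-linked genes, at 8.76 and 9.33 on average, while the other arrays had Xist between 12.99 and 13.26 and Y-linked genes between 4.02 and 4.16. Each genotype thus had 1 such array.

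Megakaryocyte genes were higher in knockout livers. A smaller share of erythroid cells alone would raise the markers of all other cells alike. The megakaryocyte list rose by 0.853 more than the mean of the hepatoblast, mesenchymal and macrophage lists (SDs 0.15 and 0.14). Those 3 lists were chosen after their falls were seen, so this difference restates those falls and does not test the explanation. Against all 8 other non-erythroid cell lists the difference was 0.64 (SDs 0.10 and 0.14). Its exact permutation p was 0.1, the lowest possible. This difference argues against a smaller erythroid share as the whole cause, although the megakaryocyte rise was known beforehand. Against granulocytes, which rose as well, it was 0.25 (SDs 0.10 and 0.20, exact permutation p = 0.2). Megakaryocytes were thus not told apart from granulocytes. All 24 changes were positive (100%), which restates the pattern, so a larger share of megakaryocytes, higher expression per cell and transcription of these genes in other precursors could not be told apart. Under 3 scalings at least 17 of the 24 were called higher.

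Hypoxia genes were higher too. A second list of 25 hypoxia genes, written when the first list's direction was known but these genes' values were not, had 15 of 22 measured members higher and 1 lower, with a median of 0.47 (camera p = 2.07e-10; p = 0.00737 with an estimated correlation, unadjusted, where the first list had 0.00612, or 0.153 adjusted over the 25 lists), which is consistent with a hypoxia program. A larger share of liver parenchyma would raise the hepatoblast list as well, but the mean of that list lay 0.16 lower in the knockout. The hypoxia list rose by 0.728 more than it (SDs 0.16 and 0.07, exact permutation p = 0.1, the lowest possible). Both directions were known beforehand, so this difference restates them. Under 3 scalings at least 13 hypoxia genes were called higher, against 16. Low oxygen in anaemic embryos and a direct effect of Klf1 loss in erythroid cells could not be told from these arrays, and neither was tested.

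Solute carrier genes made up 12 of the 207 genes that fell at least 2-fold, or 5.8%, against 1.83% of all genes tested (Fisher's exact test, 1-sided, p = 0.000443), and 2 of those that rose (p = 0.574). The count was prompted by Slc22a4 and Slc43a1 among the 12 largest falls, and they are part of it, so this p partly restates what was seen. Without the 12 largest falls, 10 of 195 were solute carriers (exact p = 0.00309), and without all members of the gene lists as well, 7 of 156 (4.49%, against 1.81%; exact p = 0.0236). Against the 12993 genes bright enough in wildtype to count, p for all 12 was 0.000451. The family was picked after the falls were seen and its genes are not independent of each other, so whether it was more frequent than chance cannot be told here.

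Genes next to Klf1 might carry variants of the strain in which the gene was altered. Of the 100 nearest genes measured, 50 on each side, 26 were called, against 19.1% of the others (Fisher's exact test, 1-sided, p = 0.0553). This window was 1 of 4 that were looked at: 10, 25 and 100 genes on each side gave exact p = 0.549, 0.235 and 0.00625, and these 4 p-values were not adjusted for each other. In these 3 windows 20, 24 and 26.5% of the genes were called, against 19.0 to 19.1% of the others. The share was thus above that of the others in every window, and the smaller windows hold fewer genes. The choice of window decides whether p falls under 0.05, so variants near the gene cannot be told apart from other causes here.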
